A study of Mus musculus with 24 samples.

How the data were processed

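The data were poly(A)-selected RNA sequencing of thoracic aorta from adult male C57BL/6 mice aged 10 to 12 weeks, per the labels. For 3 weeks 1 group ate chow with celecoxib at 100 mg/kg/day, another ate chow with rofecoxib, dosed at 50 mg/kg/day, and the control group ate chow without drug. Every mouse was injected with interleukin-1β at 10 ug/kg, 4 h before collection at zeitgeber time 11, per the labels' protocols. There were 8 libraries in each of the 3 groups, and the labels call them biological replicates. Groups and replicate numbers were taken from the sample labels. The libraries came from the TruSeq RNA kit and their construction was spread over 3 days, per the labels' protocols, but the day of each library was not given in the sources used here.

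The authors deposited 1 table of whole-number read counts per gene for 24 libraries, and these deposited counts were the values used. CASAVA 1.8.1, STAR 2.5.1b and the mm9 genome build are named in the submitters' processing notes. The counter, the annotation and the strand setting were not given in the sources used here, so reads of overlapping or antisense genes were treated as not separable. The table held 25941 genes, of which 805 had no read in any library. Library totals lay between 21668798 and 21700121 reads, a range of 0.145% of the lowest, closer than sequencing alone usually leaves them; whether and how the totals were made alike was not given in the sources used here, so the depth before any such step is unknown. The table held no gene of the mitochondrial genome and 10 Y-linked genes. Gene positions are given as the table gives them, on mm9; whether its starts count from 0 or 1 was not stated. Current symbols were matched by gene identifier for 24179 genes and used for names only; 116 symbols were carried by more than 1 row.

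Gene tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, the default expression filter, which left 14528 genes, and the quasi-likelihood test with 1 mean per group fitted on all 24 libraries. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. The common biological coefficient of variation was 19.6%. Standard errors and 95% intervals of log2 fold changes came from the same fit. CPM values are means with SD over 8 libraries after TMM scaling. A joint test asked whether either drug group differed from control. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01; lists with fewer than 5 tested genes were left out, which gave 32 tested lists. The level of a list in a library was the mean log2 CPM of its tested members, compared between groups by a two-sided exact permutation test of 8 against 8 libraries, whose smallest possible p is 0.00016, adjusted over 105 tests.

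The test design, 36 gene lists and the rule for naming genes were chosen before the data were examined. The lists held 630 distinct symbols, which matched 612 distinct genes in the table. Some genes, such as Dusp1, were in more than 1 list. Named genes were the 12 with the largest rise and the 12 with the largest fall among called genes with a mean of at least 1 CPM. Added to them were up to 4 called members of each list with the smallest p, or otherwise up to 2 members as values, and 12 fixed genes of prostanoid, endothelial, inflammatory, brown fat and smooth muscle biology. Where fewer than 5 genes passed in a direction, the 5 with the smallest p in that direction were also named. Hmgcs1 and the transcripts of the mitochondrial genome were not analysed here. Some genes that this rule names are not reported here. Alternatives were RLE size factors, library size alone, no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, limma voom with sample weights and only the groups compared. Others were the replicate number as a block, brown adipocyte and skeletal muscle levels as covariates, 2 surrogate variables from sva 3.50.0, an estimated correlation per list and the fry test. Chosen after the data were seen were replicates 1 to 4 and 5 to 8 as a batch term or alone, 3 covariates for general adipocyte, nerve and macrophage levels, and leaving out each library in turn.

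The scripts were tested on negative binomial counts simulated with the means, totals and spread of these libraries, with 50 genes at each of 4 fold sizes. For celecoxib against control on 14435 genes, 24% of genes changed 1.25-fold, 66% changed 1.5-fold and 98% changed 2-fold were recovered, with 10 false calls. For rofecoxib against control on 14435 genes, the shares were 36%, 74% and 84%, with 6 false calls. A simulated list, heat shock genes shifted by 0.3 (log2), was recovered by camera at an adjusted p of 5.42e-13, and 1 other of 32 lists was called. Each gene was drawn independently, so this did not test camera on correlated genes. In the real libraries the estimated correlation of the heat shock list was 0.447. Replicates were compared by a chi-square over 14329 genes: the 84 pairs within groups differed by 8.86 to 87.5 per gene, so no pair was alike within sampling noise.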

Results

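Thoracic aortas of mice given celecoxib, rofecoxib or plain chow for 3 weeks were profiled by RNA sequencing 4 h after an injection of interleukin-1β, a cytokine that induces prostaglandin synthesis. Both drugs selectively inhibit cyclooxygenase-2, the product of Ptgs2; celecoxib carries a sulfonamide and rofecoxib a methylsulfone. The doses differed, 100 mg/kg/day for celecoxib and 50 mg/kg/day for rofecoxib, so the drugs were compared at these doses and not at matched ones. Each group held 8 libraries, and each library had between 21668798 and 21700121 counted reads. All mice received interleukin-1β, so the effect of the cytokine itself was not measured.

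The first comparison asked which transcripts differed between celecoxib and control aortas. Ddit4, an inhibitor of mTORC1 signalling that stress and glucocorticoids induce, fell with celecoxib from 82.7 ± 13.0 to 32.3 ± 10.3 CPM (SD, n = 8 each), a log2 fold change of -1.36 (SE 0.22), and was below every control in 8 of 8 libraries. Gadd45g, a stress-induced growth arrest gene, fell by 0.81 (SE 0.13), Rhbdd2, a rhomboid-related gene, by 0.58 (SE 0.11) and Dusp1, a phosphatase that switches off MAP kinases, by 0.45 (SE 0.08) on the log2 scale. Pms2, a DNA mismatch repair gene, rose by 0.35 (SE 0.06). These were the 5 genes called of 14528 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1 higher and 4 lower, at adjusted p of 0.020 for Ddit4 and Gadd45g, 0.031 for Pms2 and 0.043 for Dusp1 and Rhbdd2. An unadjusted p under 0.05 was reached by 1969 genes. Ddit4 lies on chromosome 10 from 59412221 to 59414720 (ENSMUSG00000020108) and Dusp1 on chromosome 17 from 26642333 to 26645666 (ENSMUSG00000024190), on mm9. DESeq2 called 110 genes, 67 higher and 43 lower, and limma voom 121, 71 higher and 50 lower, so the balance of directions depended on the method. The count was 2 without a filter, 45 in the fit of these groups alone, 9 with brown adipocyte and skeletal muscle covariates, 21 with 3 covariates, 27 with the replicate number as a block, 174 (69 higher, 105 lower) with a batch term for replicates 1 to 4 and 5 to 8, and 9 and 313 within these sets. Leaving out 1 library gave 34 (celecoxib replicate 2), 9 (rofecoxib replicate 8) or 3 (celecoxib replicates 1 and 4, rofecoxib replicates 1, 2 and 6, control replicates 1 and 8, each in turn). It gave 2 (control replicates 5 and 6), 1 (celecoxib replicate 5, control replicate 2) or 0 by edgeR (celecoxib replicates 7 and 8, control replicates 3 and 4, with 1490 to 2058 genes at an unadjusted p under 0.05). Ddit4 kept its call in 20 of these 24 fits and Dusp1 in 7. Scaling by library size alone called 7 genes, 3 higher and 4 lower.

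Several genes lay just short of the threshold with celecoxib and are given as values. Depp1 (8430408G22Rik in the table) had a log2 fold change of -0.96 (SE 0.18, edgeR adjusted p = 0.051). On the higher side were Ccn5 (Wisp2 in the table) at 0.58, Rasl11a at 0.55, Intu at 0.45 and Msmo1 (Sc4mol in the table), an enzyme of cholesterol synthesis, at 0.45, with edgeR adjusted p of 0.0795 for Ccn5 and 0.0874 for the others. Cyp51, lanosterol demethylase of cholesterol synthesis, was at 0.49 (SE 0.11, edgeR adjusted p = 0.105).

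Among the gene lists, 12 of 32 were called by camera for celecoxib against control, 1 higher and 11 lower, and 0 kept the call with an estimated correlation, while 2 were called by fry. The glucocorticoid-responsive list was lower, with 13 of its 14 members below 0 and a median log2 fold change of -0.35. Of these, 1 member, Dusp1, passed over all genes and 3 passed when adjusted over the list alone (camera adjusted p = 3.37e-07, and adjusted p = 0.063 with an estimated correlation). The acute interleukin-1 and NF-kB list had 35 of 36 members below 0 and a median of -0.47, with 0 members called by edgeR and 10 at an unadjusted p under 0.05. Cxcl2, a neutrophil chemokine, was at -1.76 (SE 0.63) and Il6 at -1.37 (SE 0.51, 22.5 ± 17.2 against 58.0 ± 35.5 CPM, n = 8 each), edgeR adjusted p of 0.245 and 0.256. Its camera adjusted p was 8.63e-09 (adjusted p = 0.575 with an estimated correlation). The interferon list had 23 of 24 members below 0, a median of -0.32 and 0 called members, with 9 members at an unadjusted p under 0.05 (camera adjusted p = 3.37e-07, and adjusted p = 0.575 with an estimated correlation). Neutrophil markers had 10 of 10 members below 0 at a median of -0.84, with 0 called over all genes, 6 at an unadjusted p under 0.05 and 4 lower when adjusted over the list alone (camera adjusted p = 2.25e-05, and adjusted p = 0.575 with an estimated correlation). Immediate early genes had 16 of 21 members below 0 at a median of -0.42, with 1 called lower over all genes, Dusp1, and 3 lower when adjusted over the list alone (camera adjusted p = 5.94e-05, and adjusted p = 0.575 with an estimated correlation). Cytosolic ribosomal protein genes had 20 of 20 members above 0 at a median of 0.11, with 0 called and 6 at an unadjusted p under 0.05 (camera adjusted p = 2.17e-06, and adjusted p = 0.590 with an estimated correlation).

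The other 6 lists called by camera with celecoxib were lower and had 0 members called over all genes. Macrophage markers had 14 of 15 members below 0 at a median of -0.20, general adipocyte markers 16 of 17 at -0.32, Schwann cell markers 10 of 11 at -0.73 and erythroid and platelet genes 9 of 10 at -0.38. Extracellular matrix genes had 18 of 26 below 0 at -0.14 and xenobiotic metabolism genes 13 of 17 at -0.26. In that order the camera adjusted p were 0.00946, 0.0421, 0.0330, 0.0270, 0.0160 and 0.0421, and with an estimated correlation 0.697 for general adipocyte markers and 0.590 for the others. The levels of macrophage and general adipocyte markers were lower within replicates 1 to 4, by -0.49 and -0.55, but turned to 0.04 and 0.07 within replicates 5 to 8.

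**Figure D1:**
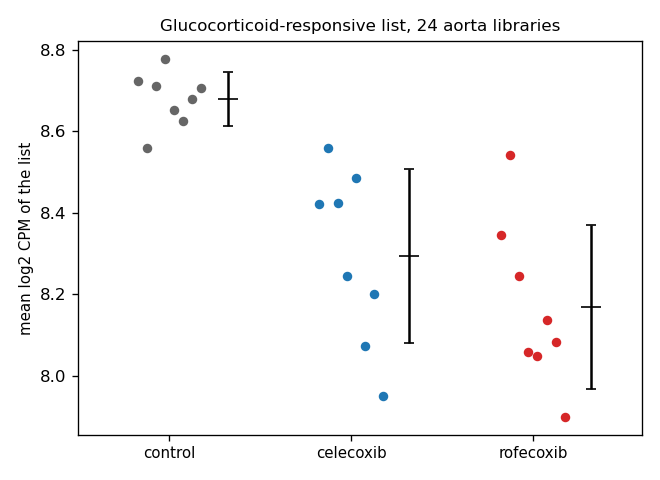
Mean log2 CPM of the 14 glucocorticoid-responsive genes in each of the 24 aorta libraries, by diet group; points are libraries and the black bar is the group mean with SD. The control libraries average 8.68 with an SD of 0.067, celecoxib 8.30 with an SD of 0.21 and rofecoxib 8.17 with an SD of 0.20.

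The level of the glucocorticoid-responsive list in each library separated both drug groups from control. It was 8.30 ± 0.21 with celecoxib and 8.68 ± 0.067 in control (mean log2 CPM, SD, n = 8 each), a difference of -0.38, with 7 of 8 celecoxib libraries below every control (exact permutation p = 0.00031, adjusted p = 0.011). With rofecoxib it was 8.17 ± 0.20, a difference of -0.51, with 8 of 8 libraries below every control (exact permutation p = 0.00016, the smallest possible, adjusted p = 0.0082). Within replicates 1 to 4 the differences were -0.28 for celecoxib and -0.40 for rofecoxib, and within replicates 5 to 8 they were -0.49 and -0.62. Celecoxib and rofecoxib differed in this level by 0.13 (exact permutation p = 0.242). Both tests against control used the same 8 control libraries, so they are not independent of each other.

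The second comparison asked which transcripts differed between rofecoxib and control aortas. Dusp1 fell with rofecoxib from 183 ± 16.3 to 119 ± 16.2 CPM (SD, n = 8 each), a log2 fold change of -0.62 (SE 0.08, edgeR adjusted p = 0.00046). Cyp51 rose from 21.3 ± 2.70 to 35.9 ± 5.85 CPM, a log2 fold change of 0.75 (SE 0.11, edgeR adjusted p = 0.0011), and both were beyond every control in 8 of 8 libraries. Arrdc2, an arrestin-domain gene, fell by 1.21 (SE 0.19), Vwce, a von Willebrand factor domain gene, by 1.57 (SE 0.29), Fzd9, a Wnt receptor, by 1.67 (SE 0.32) and Klf2, a flow-responsive transcription factor of endothelium, by 0.73 (SE 0.12). Lep, which encodes the adipocyte hormone leptin, rose by 2.26 (SE 0.43), and the peptide gene Apln and its receptor gene Aplnr rose by 2.18 (SE 0.45) and 1.59 (SE 0.30). Cyp51 lies on chromosome 5 from 4080943 to 4104948 (ENSMUSG00000001467) on mm9.

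In all, 1008 genes were called for rofecoxib against control, 563 higher and 445 lower, of which 72 changed more than 2-fold and 716 less than 1.5-fold. Scaling by library size alone called 1416, 1106 higher and 310 lower. The count rose to 1812 by DESeq2, 2448 by limma voom and 1735 with a batch term for replicates 1 to 4 and 5 to 8. It fell to 557 without a filter, 82 with brown adipocyte and skeletal muscle levels as covariates, 71 with 3 covariates, 26 with 2 surrogate variables, 42 in replicates 1 to 4 alone and 401 in replicates 5 to 8 alone. Leaving out 1 library gave 536, 532, 383 and 1945 (rofecoxib replicates 2, 4, 7 and 8) and 465, 358, 1789, 596, 504 and 426 (control replicates 1, 2, 4, 5, 6 and 7). Of the 71 called genes named by the rule, 33 kept their call without any 1 library, and Dusp1 kept it under every alternative.

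Genes of cholesterol synthesis rose with rofecoxib: 9 of 18 measured members of the lipogenesis and sterol list rose, 7 of them from its 9 sterol genes, 0 fell and 12 rose when adjusted over the list alone. Of the other 9 members, the desaturase gene Scd2 rose by 1.09 (SE 0.22) and the transcription factor gene Srebf1 by 0.34 (SE 0.10), while Fasn was at 0.36 (SE 0.45, edgeR adjusted p = 0.615). Besides Cyp51, the isoprenoid enzyme gene Idi1 rose by 0.72 (SE 0.12) and farnesyl diphosphate synthase gene Fdps by 0.48 (SE 0.09), each above every control in 8 of 8 libraries. The list was called by camera (adjusted p = 3.78e-08, and adjusted p = 0.258 with an estimated correlation), and its level was higher by 0.49 (exact permutation p = 0.00901, adjusted p = 0.0723). The general adipocyte list was also higher in these libraries, by 0.75 in mean log2 CPM (exact permutation p = 0.035, adjusted p = 0.115).

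Glucocorticoid-responsive genes fell with rofecoxib, 7 of 14 over all genes and 9 adjusted over the list alone, with 0 rising. Zbtb16 fell by 0.99 (SE 0.25), Errfi1, a feedback inhibitor of EGF receptor signalling, by 0.94 (SE 0.22), Fkbp5, a co-chaperone of the glucocorticoid receptor, by 0.82 (SE 0.20) and the kinase gene Sgk1 by 0.51 (SE 0.10). The list's camera adjusted p was 1.67e-07, and it was the 1 list of 32 that kept its call for rofecoxib with an estimated correlation (adjusted p = 0.047). Camera called 14 lists in all, 8 higher and 6 lower, and fry called 4. With the fat and muscle covariates, 1 of the 14 members passed over all genes, Dusp1 at -0.60 (SE 0.09). Zbtb16 was then at -1.23 (SE 0.29), Errfi1 at -0.78 (SE 0.24), Fkbp5 at -0.77 (SE 0.23) and Sgk1 at -0.44 (SE 0.11), with edgeR adjusted p of 0.0541, 0.107, 0.107 and 0.0638. Their standard errors were wider than without the covariates, and the log2 fold change was nearer 0 in 3 of these 4 and further from it in Zbtb16.

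The cytokine-response lists that were lower with celecoxib were also lower with rofecoxib by camera. The acute interleukin-1 and NF-kB list had 25 of 36 members below 0 at a median of -0.28, but its 1 called member, Il1b, rose by 1.22 (SE 0.33; camera adjusted p = 0.00874, and adjusted p = 0.758 with an estimated correlation). The interferon list had 20 of 24 below 0 at -0.15 with 0 called (camera adjusted p = 0.0210, and adjusted p = 0.758 with an estimated correlation). Its level differed by 0.00 within replicates 1 to 4 and -0.41 within replicates 5 to 8. Immediate early genes had 16 of 21 below 0 at -0.31 with 3 called lower (camera adjusted p = 0.000801, and adjusted p = 0.573 with an estimated correlation). The levels of these lists differed between celecoxib and rofecoxib by -0.23, -0.17 and -0.01, in that order (exact permutation p = 0.420, 0.380 and 0.953). The direction turned between replicates 1 to 4 and 5 to 8 for the interferon list, from -0.54 to 0.19, and for immediate early genes, from 0.10 to -0.11.

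By camera, adipocyte and endothelial markers were higher with rofecoxib and smooth muscle genes lower, but the levels did not pass after adjustment. They differed by 0.75, 0.31 and -0.21 for general adipocyte, endothelial and smooth muscle lists (exact permutation p = 0.0348, 0.0531 and 0.0294, adjusted p = 0.115, 0.155 and 0.115). Rofecoxib replicate 8 lay on the other side of the control mean in all 3, at 6.02, 5.002 and 10.22 against 6.68, 5.43 and 10.09. Without it the differences were 0.95, 0.41 and -0.26. Of 17 general adipocyte markers, 4 rose (9 adjusted over the list alone), among them Fabp4, a fatty acid binding protein gene, from 860.5 ± 384 to 1574 ± 555 CPM, and Pparg, the master regulator of adipocytes, by 1.19 (SE 0.36). The camera adjusted p was 0.00034 (adjusted p = 0.573 with an estimated correlation), and Fabp4 kept its call in 10 and Pparg in 12 of the 24 fits that each left out 1 library. Of 13 brown adipocyte markers, 3 rose (4 adjusted over the list alone), with Fabp3 at 1.09 (SE 0.27; camera adjusted p = 0.0036, and adjusted p = 0.573 with an estimated correlation), while Ucp1 was at 1.19 (SE 0.50, edgeR adjusted p = 0.126). Fatty acid oxidation genes rose in 5 of 21 and fell in 1, with 14 higher and 1 lower adjusted over the list alone. Ehhadh, a peroxisomal enzyme gene, rose by 0.77 (SE 0.16), and the list's camera adjusted p was 0.00034 (adjusted p = 0.573 with an estimated correlation). Endothelial markers rose in 3 of 17, including the angiopoietin receptor gene Tek by 0.49 (SE 0.11) and Kdr by 1.09 (SE 0.29), also 3 adjusted over the list alone (camera adjusted p = 0.0087, and adjusted p = 0.720 with an estimated correlation). Contractile smooth muscle genes were below 0 in 16 of 16, with Synpo2 lower by edgeR and 0 adjusted over the list alone (camera adjusted p = 0.00057, and adjusted p = 0.573 with an estimated correlation). Extracellular matrix genes fell in 4 of 26 (9 lower and 1 higher adjusted over the list alone), among them collagen gene Col1a2 by 0.45 (SE 0.10; camera adjusted p = 0.0013, and adjusted p = 0.573 with an estimated correlation).

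Genes of prostanoid metabolism changed in 5 of 20 with rofecoxib, 3 higher and 2 lower (7 and 4 adjusted over the list alone). Ptgs2 itself fell from 135 ± 34.4 to 81.9 ± 25.8 CPM, a log2 fold change of -0.72 (SE 0.22, edgeR adjusted p = 0.049), and Ptgis, the prostacyclin synthase gene, fell by 0.36 (SE 0.10, edgeR adjusted p = 0.035). Tbxas1, the thromboxane synthase gene, rose from 1.10 ± 0.294 to 2.02 ± 0.883 CPM, a log2 fold change of 0.87 (SE 0.25, edgeR adjusted p = 0.036). With celecoxib the log2 fold changes were -0.29 (SE 0.22) for Ptgs2, -0.08 (SE 0.10) for Ptgis and 0.06 (SE 0.25) for Tbxas1, and 0 of 20 list members passed the edgeR test, 2 of them reaching an unadjusted p under 0.05. The direct difference of celecoxib minus rofecoxib was 0.43 for Ptgs2 (95% interval -0.02 to 0.89), 0.28 for Ptgis (0.07 to 0.49) and -0.81 for Tbxas1 (-1.32 to -0.30), with edgeR adjusted p of 0.245, 0.093 and 0.055, so none was called. The list as a whole was not called for either drug. Of the 24 fits that each left out 1 library, the Ptgs2 call was kept in 8, and was lost without celecoxib replicate 1, 3, 4 or 6, rofecoxib replicates 2 to 7 or control replicate 1, 2, 5, 6, 7 or 8. The Ptgis call was kept in 14 and the Tbxas1 call in 15; both were lost without rofecoxib replicate 1, 2, 5 or 7 or control replicate 1, 2, 5, 6 or 7, and Ptgis also without rofecoxib replicate 4. Over all alternatives the highest adjusted p was 0.550 for Ptgs2, 0.376 for Ptgis and 0.530 for Tbxas1. The macrophage list, whose cells express Tbxas1, was higher with rofecoxib by 0.32 in mean log2 CPM (exact permutation p = 0.0861, adjusted p = 0.201), with 15 of 15 members above 0 (camera adjusted p = 0.00874, and adjusted p = 0.758 with an estimated correlation).

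**Figure D2:**
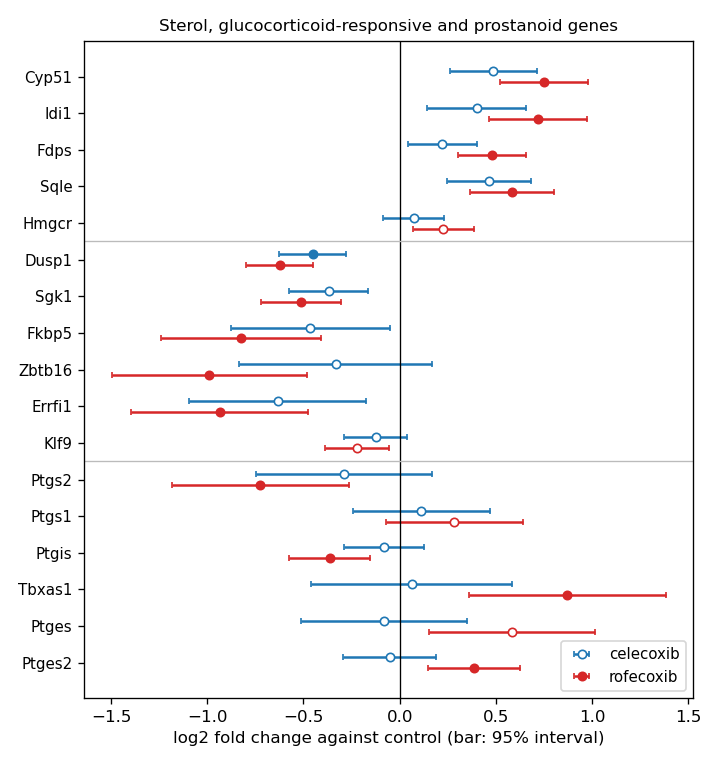
Log2 fold change against control, with 95% intervals, of sterol synthesis genes, glucocorticoid-responsive genes and prostanoid genes for celecoxib (blue) and rofecoxib (red), n = 8 libraries per group; filled points passed the edgeR test and the genes drawn were chosen after their values were seen. Cyp51 lies at 0.49 with celecoxib and 0.75 with rofecoxib, and Dusp1 at -0.45 and -0.62.

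The third comparison set celecoxib against rofecoxib directly, at their different doses. Adipocyte genes were lower with celecoxib: of 17 general adipocyte markers 11 were lower and 0 higher (16 lower adjusted over the list alone). Lpl, the lipoprotein lipase gene, was at 297 ± 107 against 746 ± 310 CPM (SD, n = 8 each) and Plin1, a lipid droplet gene, at -1.40 (SE 0.34). Ucp1, the uncoupling protein of brown fat, was at 125 ± 71.1 against 486 ± 322 CPM, a log2 fold change of -1.96 (SE 0.51, 95% interval -3.02 to -0.90). Neutrophil markers were lower in 7 of 10 (9 adjusted over the list alone), including the chemokine receptor gene Cxcr2 at -1.81 (SE 0.41), and the cytokine gene Il1b was at -1.74 (SE 0.34). The neutrophil level was low, at 0.63 log2 CPM with celecoxib and 1.76 with rofecoxib. Other lists moved too. Macrophage markers were below 0 in 15 of 15, with 5 called (12 adjusted over the list alone). Erythroid and platelet genes were below 0 in 10 of 10, with 0 called. Contractile smooth muscle genes were above 0 in 15 of 16, with 0 called over all genes and 8 higher adjusted over the list alone. Schwann cell markers were lower in 4 of 11, all 11 when adjusted over the list alone, and their mean level ran from 1.23 to 6.20 among the rofecoxib libraries. Among called genes with a mean of at least 1 CPM, the largest difference on the higher side was Actn2, a sarcomere gene, at 1.10 (SE 0.31), followed by Tcp11 at 0.77 (SE 0.19). Actn2 rested on celecoxib replicate 2, at 46.3 CPM with the next celecoxib library at 15.3 CPM. Without it the log2 fold change was 0.57 (edgeR adjusted p = 0.108), and the mean of the cardiac markers in that library was 6.69 log2 CPM.

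The genes called above were among 710 called between the drugs, 82 higher and 628 lower with celecoxib, of which 180 differed more than 2-fold. The calls lay close to the threshold: Ucp1 and Lpl had edgeR adjusted p of 0.038 and 0.037. The count was 0 in the edgeR fit of these groups alone, where 2816 genes had an unadjusted p under 0.05, and 1419 by DESeq2. It was 2073 within replicates 1 to 4 and 0 by edgeR within replicates 5 to 8 (896 at an unadjusted p under 0.05) and with the replicate number as a block (3169). The edgeR count was also 0 without a filter (4367), with fat and muscle covariates (1631), with 3 covariates (539) and with 2 surrogate variables (798). Leaving out 1 library gave 0, 0, 2 and 1 (celecoxib replicates 2, 3, 4 and 5), 240, 0, 0, 3, 0 and 1997 (rofecoxib replicates 1, 2, 3, 4, 7 and 8) and 447 and 363 (control replicates 2 and 6). Where this edgeR count was 0, 2824 to 3250 genes had an unadjusted p under 0.05, and 0 of the 66 called genes named by the rule kept their call in all 24 such fits. Of 32 lists, 15 were called by camera, 4 higher and 11 lower, and 11 by fry, but 0 with an estimated correlation. The general adipocyte and neutrophil lists had camera adjusted p of 2.57e-09 and 1.09e-07 (adjusted p = 0.279 for each with an estimated correlation), and the nerve list 4.69e-05 (adjusted p = 0.346 with an estimated correlation).

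**Figure D3:**
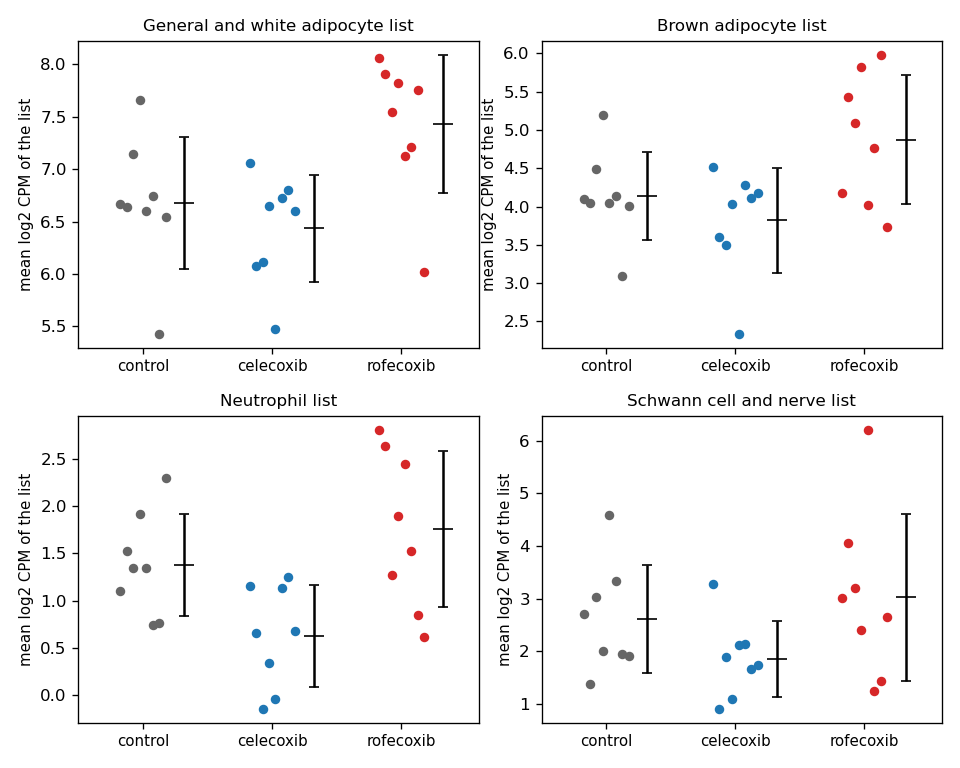
Mean log2 CPM of general adipocyte, brown adipocyte, neutrophil and Schwann cell and nerve markers in each of the 24 libraries, by diet group; points are libraries and the black bar is the group mean with SD. The general adipocyte level averages 6.68 in control, 6.44 with celecoxib and 7.43 with rofecoxib, with overlapping libraries.

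Levels of these marker lists overlapped between the drugs and did not pass after adjustment. The general adipocyte level was lower with celecoxib by a log2 difference of -0.99 (exact permutation p = 0.0064, adjusted p = 0.072), -1.36 within replicates 1 to 4 and -0.63 within replicates 5 to 8. The neutrophil level differed by -1.13 (exact permutation p = 0.0076, adjusted p = 0.072) and the brown adipocyte level by -1.05 (exact permutation p = 0.0154, adjusted p = 0.0927). Of 105 level tests, 4 passed: the glucocorticoid-responsive list for each drug, and mesothelial and epithelial markers in a pair of comparisons. The latter rested on Cdh1 and Krt18 alone and differed for rofecoxib against control at 0.63 (exact permutation p = 0.00047, adjusted p = 0.012) and for celecoxib against rofecoxib at -0.71 (exact permutation p = 0.00016, adjusted p = 0.0082). For rofecoxib against control 2 of 2 genes were above 0. Between the drugs 1 gene was called lower and the other was above 0. The level was low, at 0.71 log2 CPM with rofecoxib, 0.079 in control and -0.001 with celecoxib.

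The final comparison asked how far the drugs shared a response. The 5 genes called with celecoxib were all called in the same direction with rofecoxib, against 0.039 higher and 0.123 lower for independent lists, a value that leaves out the shared controls. In 20 simulations that drew all 24 libraries, the 8 shared controls included, with no change between groups, 0 genes were called in either comparison. They gave no overlap to set beside the observed one. All simulations of unchanged groups here drew each gene independently. They leave out the correlation between genes and are not a full reference for unchanged groups. Of the 1008 genes called with rofecoxib, 885 (87.8%) had the same sign with celecoxib, against a mean of 88.8% among as many genes of smallest p in those simulations. Over all genes the signs agreed in 67.2%, against 66.7% in simulated unchanged groups. Among those called that rose with rofecoxib, the median log2 fold change was 0.43 with rofecoxib and 0.11 with celecoxib. Among those that fell it was -0.37 and -0.16. The genes were selected by their rofecoxib call, which favours larger values with rofecoxib. Across all genes, which are not independent replicates, differences of mean log2 CPM from control correlated at r = 0.440, against 0.499 for simulated unchanged groups, whereas the covariance was 0.0320 against 0.0168 in the simulation. With the controls split between the drugs, r was 0.028 or 0.402 depending on which replicates served which drug, and the covariance 0.0028 or 0.0302. In the direct test, 213 of the 1008 genes differed between the drugs, 174 of them higher with rofecoxib. A joint test of both drugs called 1107 genes, and 2259 by DESeq2, 2654 by limma voom, 1896 with the batch term, 355 without a filter and 314 within replicates 5 to 8. It called 91 with 3 covariates, 53 with fat and muscle covariates and 28 with 2 surrogate variables. Leaving out 1 library gave 489, 506 and 554 (celecoxib replicates 3, 4 and 5), 643, 228, 245, 211 and 2434 (rofecoxib replicates 1, 2, 4, 7 and 8) and 267, 273, 493, 373 and 633 (control replicates 1, 2, 5, 6 and 7).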

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

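The test of single control libraries for the glucocorticoid list, the median test of the adipocyte list and the choice of the sterol genes as a subset were made after the results were seen.

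Of 111 groups of libraries checked with Dixon's test, 8 held a library apart from the rest, and chance gives about 1 in 20. Skeletal muscle markers stood at 2.40 in control replicate 3 (mean log2 CPM), against 0.74 in the next library, and at 1.91 in celecoxib replicate 2, against 0.92. Brown adipocyte markers were lowest in celecoxib replicate 5, at 2.34 against 3.50 in the next. In rofecoxib replicate 8 general adipocyte markers were at 6.02 against 7.12 in the next library, mast cell markers at 0.53 against 1.60 and carbonic anhydrases at 2.57 against 3.13. In rofecoxib replicate 5 mesothelial and epithelial markers were at 1.21 against 0.76 in the next library, and circadian clock genes at 5.20 against 5.63. Among named genes, 54 of 651 groups held such a library.

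The glucocorticoid-responsive list was lower with both drugs than in control. With brown adipocyte and skeletal muscle covariates the medians were -0.34 (celecoxib) and -0.48 (rofecoxib), and only 1 of 14 members was then called for each drug. These values argue against brown fat, as its markers measure it, as the whole cause. The covariates left a median of -0.44 for general adipocyte markers between the drugs, which is not a test of the drop against control. General adipocyte levels differed from control by -0.24 with celecoxib and 0.75 with rofecoxib (exact permutation p = 0.425 and 0.0348, adjusted p = 0.594 and 0.115). These directions were opposite while the list fell with both drugs, so 1 common change in fat share was not seen. Neither difference passed after adjustment, so the share of other perivascular fat was not excluded for either drug alone. Replicates 1 to 4 and 5 to 8 were equally present in every group, so a shift between these sets could not by itself give the drop. The drop was at least -0.28 within each set (mean log2 CPM). Any single control library as the cause was argued against by a drop of at least -0.37 without any 1 control. A second list of 14 tested glucocorticoid-induced genes, written before its values were seen, was lower in level by -0.22 with celecoxib (exact permutation p = 0.0014; 13 of 14 below 0, 0 called) and by -0.25 with rofecoxib (exact permutation p = 0.0073; 9 of 14 below 0, 4 called), with camera p of 0.000452 and 0.00258, or 0.0400 and 0.0739 with an estimated correlation. This is consistent with lower glucocorticoid signalling as a hypothesis, but other inputs to these genes and a difference in stress or handling between groups stay open, as untested.

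Adipocyte genes were lower with celecoxib than with rofecoxib. Replicate numbers as the whole cause were argued against by a drop of -0.63 in the smaller of the 2 sets (replicates 5 to 8). With brown adipocyte and skeletal muscle covariates 0 genes differed between the drugs by edgeR, where 1631 had an unadjusted p under 0.05; the fit of the 2 drug groups alone, without covariates, also gave 0, so that count decides nothing. The median of the general adipocyte list moved from -1.16 to -0.44 with these covariates, with 16 of 17 members still below 0. A different share of perivascular fat in the dissected tissue therefore cannot be told apart from a change within fat cells, since marker levels measure both.

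Sterol synthesis genes, a subset of 9 tested genes, were higher with rofecoxib than in control, by 0.55 in mean log2 CPM, and no p is given because the subset was chosen after its rise was seen. The subset's median was 0.52 with the brown adipocyte and skeletal muscle covariates, from 0.58 without, with 9 of 9 genes above 0 and 6 called. These values argue against the share of brown fat as the whole cause. The general adipocyte level was higher with rofecoxib than in control by 0.75 without covariates. What these covariates left of it is given here only between the drugs, at a median of -0.44. The share of other perivascular fat was thus not excluded. The 2 sets of replicate numbers were equally present in every group, and the smaller rise within a set was 0.39. With celecoxib the subset was higher by 0.31, and the drugs differed by -0.24. A response of sterol synthesis to either drug may account for this but was not tested apart from the pattern itself, and food intake was not analysed here.

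Other splits of the same libraries, 100 for each result with the real one included, were compared with the gene counts. For celecoxib against control 1 split, the real one, gave as many as 5 genes, and the highest other gave 3. For rofecoxib against control 2 gave as many as 1008, the highest other being 1676, and for celecoxib against rofecoxib 2 gave as many as 710, the highest other being 1235. For the joint test 1 gave as many as 1107, the highest other being 505. For each of these the share was under 0.05, unadjusted over the results. This makes chance less likely but does not exclude it. A random split gave more calls than the real one for rofecoxib against control and for celecoxib against rofecoxib.

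Chance was not excluded for the numbers of gene lists or for the correlation between the drugs. As many lists were called in 33 splits for celecoxib against control (12, highest other 19), in 19 for rofecoxib against control (14, highest other 20) and in 16 for celecoxib against rofecoxib (15, highest other 20). A correlation as high as 0.440 came in 61 splits, with a highest other of 0.837.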

How the results depend on the processing

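The settings for replicates 1 to 4 and 5 to 8, the 3 covariates and leaving out 1 library were chosen after the data were seen. Of 142 named calls, 142 were kept by DESeq2, 140 with RLE size factors, 122 by limma voom, 53 without a filter, 17 with brown adipocyte and skeletal muscle covariates, 16 with 3 covariates and 8 with 2 surrogate variables. The replicate number as a block kept 67 of 142 and fits of only the 2 groups 62 of 139. Replicates 1 to 4 alone kept 63 of 141 and replicates 5 to 8 alone 21 of 141. Of 41 list calls, 41 were kept with RLE size factors and 1 with an estimated correlation. Fewer libraries may account for part of the loss in the replicate subsets, but neither this nor another cause was tested. Some counts rose there, to 2073 genes between the drugs in replicates 1 to 4 and to 313 for celecoxib against control in replicates 5 to 8.

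For celecoxib against control (5 genes), the count was 2 without a filter, 110 by DESeq2, 121 by voom, 45 with only the 2 groups, 27 with the replicate number as a block, and 9 with brown adipocyte and skeletal muscle covariates. It was 174 with a batch term for replicates 1 to 4 and 5 to 8, 9 in replicates 1 to 4, 313 in replicates 5 to 8 and 21 with 3 covariates. For rofecoxib against control (1008), it was 557 without a filter, 1812 by DESeq2, 2448 by voom, 82 with fat and muscle covariates, and 26 with 2 surrogate variables. It was 1735 with the batch term, 42 in replicates 1 to 4, 401 in replicates 5 to 8 and 71 with 3 covariates. For celecoxib against rofecoxib (710), it was 1419 by DESeq2, 2073 in replicates 1 to 4 and 0 by edgeR in each of 7 settings, where voom with all libraries gave 862. These were no filter (4367 genes at an unadjusted p under 0.05), only the 2 groups (2816), the block (3169), fat and muscle covariates (1631), 2 surrogate variables (798), replicates 5 to 8 (896) and 3 covariates (539). For the joint test (1107), it was 355 without a filter, 2259 by DESeq2, 2654 by voom, 53 with fat and muscle covariates, 28 with 2 surrogate variables, 1896 with the batch term, 314 in replicates 5 to 8 and 91 with 3 covariates. Same-number correlations between groups ran from -0.303 to 0.560, with 12 of 24 pairs above 0.1. Of the 24 libraries, 7 correlated best with their own number in another group. No values for pairs of unlike number, and no count by chance, are given beside these. Pairing by replicate number was thus neither shown nor excluded.

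Leaving out 1 library in turn gave 0 to 34 genes for celecoxib against control, 358 to 1945 for rofecoxib against control, 0 to 1997 for celecoxib against rofecoxib and 211 to 2434 for the joint test, and 9 to 17, 12 to 16 and 14 to 18 lists. Sign changes are given for named genes called in the main or the alternative fit. Between the drugs, Car3 (log2 0.12), Cyp4b1 (0.039) and Asns (0.10) changed sign with 3 covariates and Elovl3 (0.14) with fat and muscle covariates.

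The number of lists for celecoxib against control (12) was 0 with an estimated correlation, 2 by fry, 20 in replicates 1 to 4 and 4 in replicates 5 to 8. For rofecoxib against control (14) it was 1 with an estimated correlation, 4 by fry, 9 with fat and muscle covariates and 8 in replicates 5 to 8, and for celecoxib against rofecoxib (15) it was 0 with an estimated correlation and 11 by fry. Lists that changed direction and were called in the main or the alternative fit are given with their camera adjusted p in the alternative. Lists called in neither fit are left out. For celecoxib against control these were endothelial markers (0.00304) and adventitial fibroblast markers (0.00304) in replicates 1 to 4 and macrophage markers (0.964) in replicates 5 to 8. For rofecoxib against control they were interferon genes (0.924) and ribosomal proteins (0.0169) in replicates 1 to 4. Between the drugs they were interferon genes (0.00159), endothelial markers (0.617), adventitial fibroblast markers (0.00934) and heat shock genes (1.60e-07) in replicates 5 to 8. The correlation of the drug responses (0.440) was 0.0277 or 0.402 with split controls and 0.416 at a mean of at least 1 CPM.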

Other observations

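The gene groups below were chosen for description after their values were seen.

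Within the lipogenesis and sterol list, the celecoxib values went both ways, with 9 of 18 members above 0 and 9 below, and 6 higher when adjusted over the list alone. Beside Cyp51, Sqle, squalene epoxidase, was at a log2 fold change of 0.47 (SE 0.11, edgeR adjusted p = 0.105). Fasn, fatty acid synthase, was at -1.03 (SE 0.46, edgeR adjusted p = 0.329) and Scd1, a fatty acid desaturase, at -0.71 (SE 0.39, edgeR adjusted p = 0.418). None of these passed over all genes. The direct difference between the drugs in Fasn was -1.40 (SE 0.46, edgeR adjusted p = 0.0691).

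Cardiac muscle markers were uneven among libraries. Their mean log2 CPM was 6.69 in celecoxib replicate 2 and between 0.03 and 3.60 in the other 23 libraries. Their median log2 fold change was 2.46 for celecoxib against control (camera adjusted p = 0.0510) and 2.57 for celecoxib against rofecoxib (camera adjusted p = 0.0248, and adjusted p = 0.588 with an estimated correlation), and the level differences of 0.92 and 0.99 did not pass (exact permutation p = 0.373 and 0.271). Without celecoxib replicate 2 the level differences were 0.31 and 0.39 (exact permutation p = 0.629 and 0.538). Mast cell markers rose in 2 of 8 with rofecoxib, Cma1 by 1.02 (SE 0.25) and Tpsb2 by 0.93 (SE 0.29), with 3 adjusted over the list alone (camera adjusted p = 0.0159, and adjusted p = 0.573 with an estimated correlation).

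The number of genes with no read was 6480 ± 317 in replicates 1 to 4 and 7234 ± 309 in replicates 5 to 8 (mean, SD, n = 12 each, permutation p = 3e-05). Each group held 4 libraries of either set. The TMM factor was 1.02 ± 0.0217 with rofecoxib and 0.981 ± 0.0284 in control (SD, n = 8 each, exact permutation p = 0.00653).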
